A study of Rattus norvegicus with 11 samples.

How the data were processed

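RNA abundance was measured on 11 Affymetrix rat expression arrays, each hybridised with total RNA from the heart ventricle of Fischer-344 rats, an inbred strain widely used in ageing research. The labels place 6 arrays in an old group of 22 months and 5 in a young group of 4 months, and each array took its replicate number from its title. Nothing in the labels says whether each array came from a separate animal, so every p-value measures the spread between these samples, which may be technical.

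The deposited table holds 1 linear intensity for each of 8799 probe sets on each array, from 0.2 to 307760, with no value at or below 0. A probe set is the group of short probes that the manufacturer combined into 1 reading. The software, background correction and detection calls behind the deposited intensity values are not given in the sources used here. The mean intensity of each array, trimmed by 2% at both ends, lay between 500.47 and 500.96, so the authors' values had been scaled to a common level per array. Such scaling removes any difference in total signal between arrays, and changes are therefore relative to the other transcripts on the same array.

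The choices in this paragraph and the next were fixed before the data were examined, apart from those named as later ones. The deposited scaling was kept, because every trimmed mean lay within 5% of the median array. Intensities were raised to a floor at the 20th percentile of all values, 47.4, and put on the log2 scale. A fold change of a dim gene is understated where arrays sit at this floor. The 59 control probe sets were left out, as were probe sets whose mean log2 value over all arrays was under the 40th percentile, which left 5244 for testing. Old was compared with young in limma 3.58.1 under R 4.3.3, with lmFit, eBayes with a mean-variance trend, and Benjamini-Hochberg adjustment over all tested probe sets at a threshold of 0.05. Where a gene had several tested probe sets, the one with the highest mean stood for the gene, which gave 3206 genes. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.56.

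The 22 gene lists covered cardiac, metabolic, immune, stress, clock and cell-type groups. They were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, over lists with at least 5 tested members, with Benjamini-Hochberg adjustment over lists. Added after the data were seen were an exact two-sided permutation test of each list's mean log2 value per array, over all 462 splits of the arrays, the comparison of spike-in signal, and the count of probe sets whose groups do not overlap. Genes were named by a rule. It took up to 12 genes with the largest change in each direction among those past the threshold, together with every list member past it. Where under 5 passed in a direction, it took the 5 with the smallest p. It added a fixed set of cardiac genes where measured, of which Adrb1, Nppa, Nppb, Myh6, Myh7 and Atp2a2 were tested. Other genes, such as the examples given for a list, were chosen after their values were seen. Array quality was described by the correlation within groups, computed again for each split after the data were seen, since an array's value depends on its group, and by the 3' over 5' ratios of the GAPDH, actin and hexokinase control transcripts, compared by exact two-sided permutation tests.

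Gene symbols came from GEO's platform annotation, which gave 1 symbol for 7006 probe sets, several for 308 and none for 1426, controls aside. Of the single symbols, 6994 were matched through their gene number to the RefSeq table of assembly GRCr8, and 0 of them changed. No gene was named from a probe set with several symbols, and no coordinates are printed because no genome build belongs to the table.

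The scripts were tested on simulated data with the real probe sets' means and spreads for the comparison of old with young. In 5 runs over 5244 probe sets, with 200 changed probe sets per run, limma found 8.8% of 2-fold, 60% of 4-fold, 82.8% of 8-fold and 96% of 16-fold differences, and 31 of its 650 calls were false. A simulated shift of -0.4 in 1 list was found in 5 of 5 runs over 3206 genes, with 0 false calls in 100 tests of other lists. The simulated genes were independent of each other, so this says nothing of lists whose members vary together. The floor was not applied to the simulated values, so the shares found may be too high for dim genes.

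The alternatives chosen beforehand were other floors and filters, quantile normalization, median centring, a fit without trend, array weights, a replicate block, leaving out each array in turn, the mean of all probe sets of a gene, camera with an estimated correlation or on ranks, and a threshold of 0.1. After the data were seen, 5 more were added: the brightness of the bacterial spike-in controls as a 2-level block, the same as a covariate, each level of that block alone, and a fit without the arrays whose GAPDH ratio was over 3. Other splits of the arrays into 6 and 5 were drawn 100 times out of 462, the real one included. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.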

Results

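The series measured transcript levels in the ventricle of old and young Fischer-344 rats, with 6 arrays from rats of 22 months and 5 from rats of 4 months. Its single comparison, old against young, asked which cardiac transcripts differ with age. Differences are given as old minus young on the log2 scale, with the standard error from limma, and group means as log2 intensity with the SD.

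No single gene differed between the age groups after adjustment over all probe sets tested. The old samples had higher group levels of complement and acute phase genes and lower group levels of genes for the mitochondrial respiratory chain, fatty acid oxidation and heat shock proteins. These list calls were made at the preset correlation: with a correlation estimated from the data, 0 lists passed. A higher estimate does not account for every lost call. For fetal genes, also called at the preset 0.01, the estimate was -0.0015, and for complement it was 0.022. No list passed an exact permutation test of its mean per array after adjustment (smallest adjusted p = 0.143). For the mitochondrial list, 14 of 100 splits of the arrays gave a camera p as small. The calls of fatty acid oxidation and heat shock genes ended with the spike-in class of the arrays as a block (camera adjusted p = 0.0738 and 0.262). Of 5244 probe sets tested with limma, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.355. At an unadjusted p under 0.05 there were 394, with 178 higher and 216 lower in old, where 262.2 would be reached by chance. At the level of genes, 0 of 3206 passed, and 220 had an unadjusted p under 0.05, 102 of them higher and 118 lower in old. The old and young arrays did not overlap for 51 probe sets, 0.973% of those tested, against an expected 0.433% by chance. This count was not set against other splits of the arrays, so chance is not excluded for it. Without old replicate 5, 2 probe sets passed: one for Gsta1, a glutathione transferase singled out after its values were seen, with a difference of 3.36 ± 0.55 (SE, limma adjusted p = 0.0218), and U42719_at, with 3.92 ± 0.45 (SE, limma adjusted p = 3.81e-04). Old replicate 5 was the old array at the young level for both. It read 7.79 for U42719_at, against 10.55 to 12.48 in the other old arrays. For Gsta1 (S72505_f_at) it read 5.11 as deposited, below every young array, the lowest of which read 5.61. The fit raised this 5.11 to the floor of 5.57. With all arrays U42719_at had the smallest p of the table, with a difference of 3.27 ± 0.65 (SE), and the annotation gave it 2 gene symbols, so no gene is named.

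No array measure passed a test between the age groups once the correlations were computed again for each split, which does not show equal quality. In the test fixed beforehand, which kept each array's correlation as it was, within-group correlation passed (exact permutation p = 0.00216, adjusted p = 0.00649). Every young array lay at 0.741 or more and every old one at 0.734 or less. That test was replaced because an array's value depends on its group. The mean correlation of an array with the others of its group was 0.684 ± 0.052 (SD, n = 6) in old and 0.795 ± 0.035 (SD, n = 5) in young (exact permutation p = 0.147, adjusted p = 0.221 over 3 array measures, with the correlations computed again for each split). With all other arrays, the mean correlation was 0.599 to 0.719 in the 4 old arrays with bright spike-ins, 0.77 to 0.775 in the 2 with dim ones, and 0.716 to 0.788 in the young arrays. The bacterial spike-in controls are transcripts added to each sample. They averaged 12.4 ± 2.26 (SD, n = 6) on the log2 scale in old and 10.3 ± 0.946 (SD, n = 5) in young. The difference did not pass (exact permutation p = 0.0931, adjusted p = 0.221). The widest gap between neighbouring arrays, 1.76, set 5 bright arrays (old replicates 3 to 6 and young replicate 4) apart from 6 dim ones, although the next gap was 1.71. The median log2 intensity of the tested probe sets was 8.75 ± 0.15 (SD, n = 6) in old and 8.63 ± 0.13 (SD, n = 5) in young (exact permutation p = 0.225, adjusted p = 0.225). The GAPDH control, whose 3' over 5' ratio increases as RNA is degraded, had log2 ratios of 3.39 and 4.09 in old replicates 3 and 4 and between 0.07 and 0.77 in the other 9 arrays. In old replicates 3 and 4 the actin log2 ratios, 1.98 and 1.82, were also the highest of all arrays. Their hexokinase log2 ratios, -0.93 and -4.16, were the lowest, the opposite of what degradation gives, so the controls did not agree. The group difference in this ratio did not pass (exact permutation p = 0.351), nor did that of actin (exact permutation p = 0.292) or hexokinase (exact permutation p = 0.275), each with an adjusted p of 0.351.

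**Figure D1:**
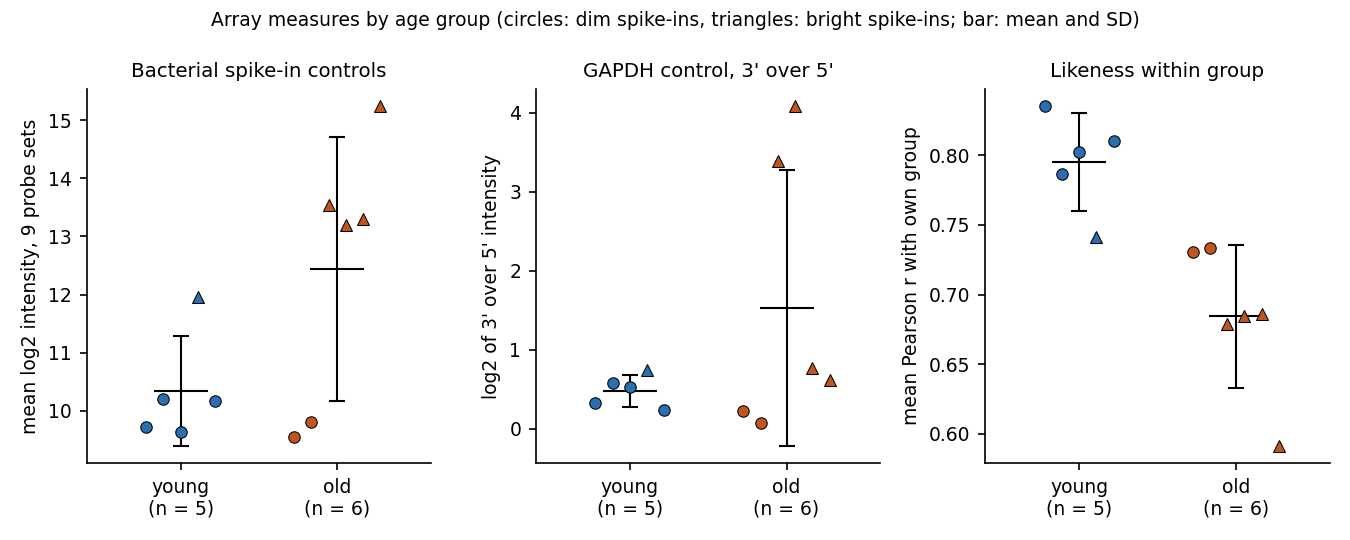
Each point is 1 array, by age group: the mean log2 intensity of 9 spike-in probe sets, the log2 of the 3' over 5' intensity of the GAPDH control, and the mean Pearson correlation with the other arrays of the group. Bars are mean and SD (young n = 5, old n = 6), triangles mark the 5 arrays with bright spike-ins, and within-group correlation averaged 0.684 in old and 0.795 in young.

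Among genes higher in old, each taken by the probe set that stands for it, the smallest p belonged to Atg16l1, which acts in autophagosome formation, with the probe set rc_AA892083_at at 9.19 ± 0.47 (SD, n = 6) in old and 7.31 ± 0.82 (SD, n = 5) in young. Its difference of 1.89 ± 0.48 (SE) had a limma adjusted p of 0.537, and the old and young arrays did not overlap. Medag (rc_AA892578_at), linked to fat cell formation, differed by 1.92 ± 0.53, and Aqp8 (AB005547_at), a water channel, by 1.98 ± 0.55. Otc (M11266_at), the ornithine transcarbamylase of the urea cycle, differed by 2.16 ± 0.61, with young replicate 4 at 7.86 and the other young arrays at 6.04 or lower, and its other probe set by 0.91 ± 0.65. Mybpc1 (X90475cds_at), the slow skeletal form of myosin-binding protein C, differed by 2.26 ± 0.63. For Mybpc1, 4 of 5 young arrays lay at the floor and young replicate 2 read 8.19.

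Among genes lower in old, Mgst3 (rc_AA892234_at), a microsomal glutathione transferase, was at 11.31 ± 0.54 (SD, n = 6) in old and 12.66 ± 0.53 (SD, n = 5) in young, a difference of -1.34 ± 0.33 (SE, limma adjusted p = 0.537). Mpst (D50564_at), which makes hydrogen sulfide from mercaptopyruvate, differed by -1.97 ± 0.49, and Evl (rc_AA997968_at), an actin-regulating protein, by -2.15 ± 0.58. Atp5f1d (U00926_g_at), a subunit of the mitochondrial ATP synthase, differed by -1.06 ± 0.30, and Anpep (AF039891_s_at), a membrane aminopeptidase, by -1.54 ± 0.45. Their other probe sets differed by -0.60 ± 0.30 and -0.56 ± 0.57. For the named probe sets of all these genes except Evl, the 6 old arrays lay below the 5 young ones, and none of the 10 genes passed.

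The receptor and cardiac marker genes chosen in advance gave mixed values. Adrb1 (D00634_at), the main beta-adrenergic receptor of heart muscle, was at 6.54 ± 0.80 (SD, n = 6) in old and 8.39 ± 0.70 (SD, n = 5) in young, a difference of -1.85 ± 0.57 (SE). All 6 old arrays lay below the young mean, and limma gave an unadjusted p of 0.00416 and an adjusted p of 0.537. Young replicate 3 read 7.16, against 8.48 or more in the other young arrays. Nppa (E00698cds_s_at), the atrial natriuretic peptide, differed by 1.18 ± 0.49 (SE), and all 4 of its probe sets were higher in old, by 1.18 to 1.87, while the probe set that stands for it differed by -0.40 ± 0.66 (SE) among the bright arrays alone. Nppb (rc_AA799498_at), the B-type peptide, differed by 0.16 ± 0.29 and turned to -0.31 ± 0.62 among the bright arrays alone. Myh6 (rc_AA891522_f_at) and Myh7 (X15939_f_at), the alpha and beta myosin heavy chains, differed by -0.25 ± 0.32 and 0.24 ± 0.31 through probe sets that can read related family members. Atp2a2 (AA799276_at), the calcium pump of the sarcoplasmic reticulum, differed by 0.02 ± 0.36 and was lower in old under 14 of 26 alternatives. The values of Nppb, Myh6, Myh7 and Atp2a2 were smaller than their standard errors, and the other 3 probe sets of Atp2a2 differed by -0.24 ± 0.37, -0.49 ± 0.40 and -1.13 ± 0.47 (SE). The other probe sets of Myh6 differed by -0.83 ± 0.59 and -1.54 ± 0.57 (SE), and that of Myh7 by 0.94 ± 0.57. None of the genes of this group passed.

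**Figure D2:**
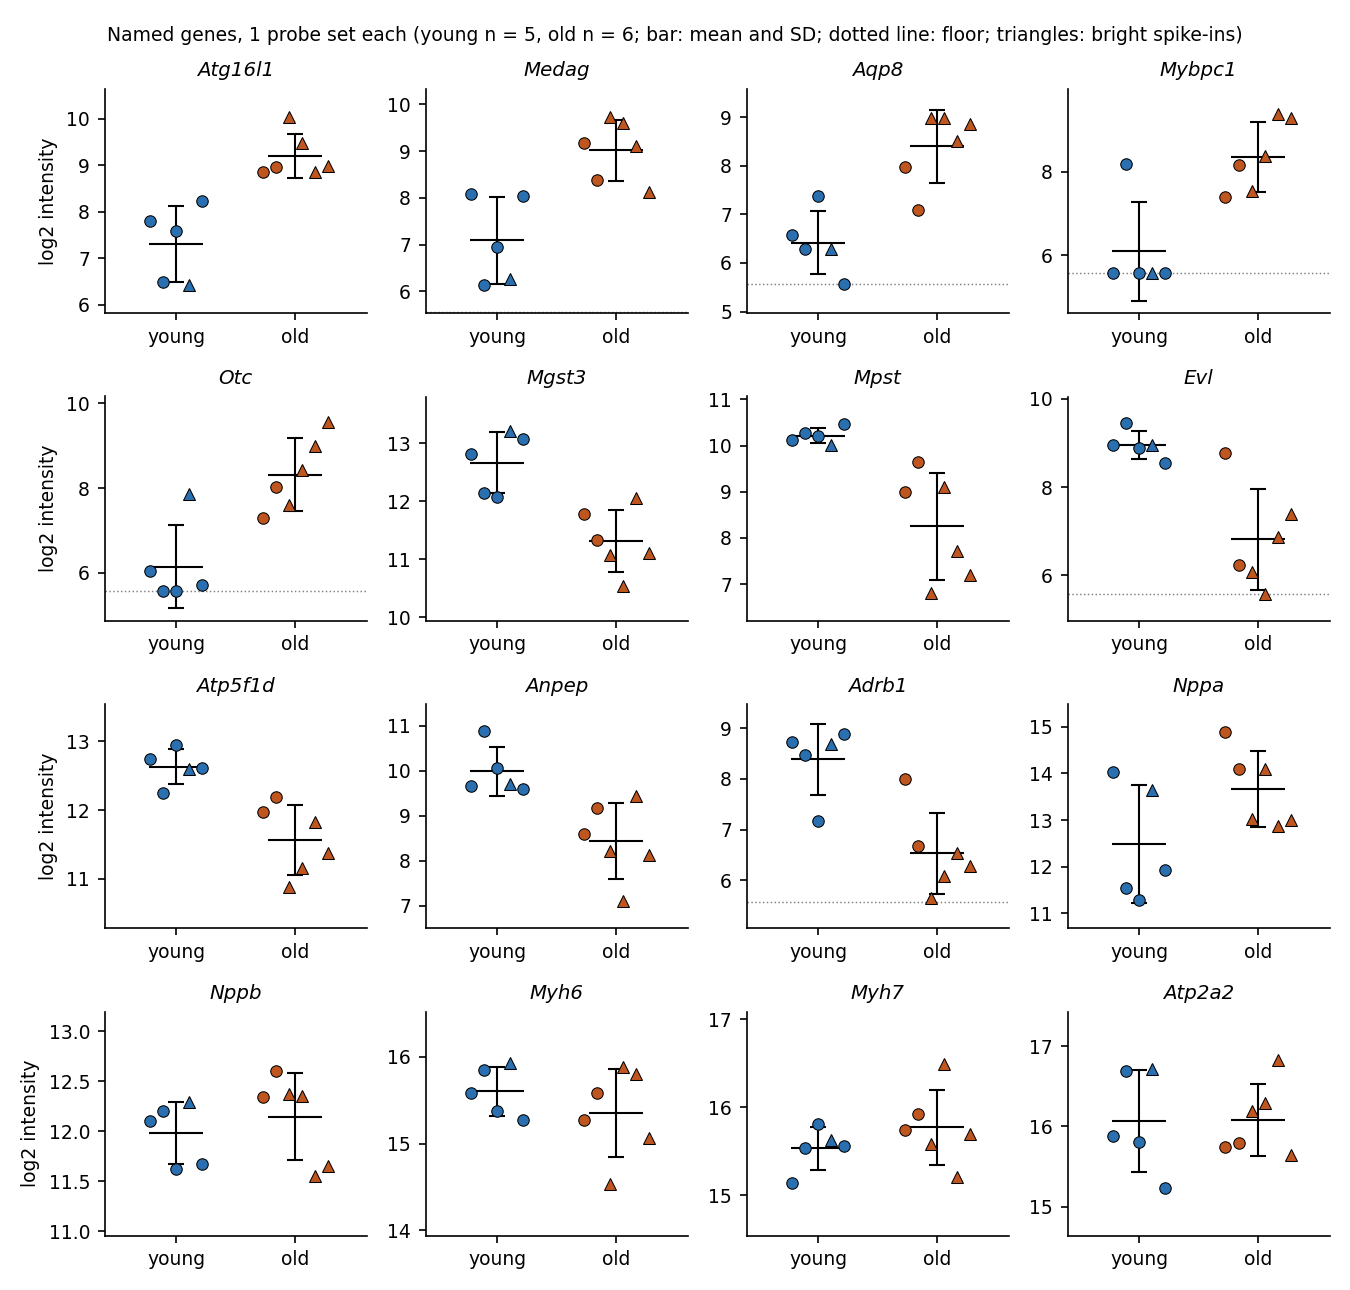
Each panel shows the log2 intensity of 1 gene's probe set in every array, by age group, with bars for mean and SD (young n = 5, old n = 6); the dotted line is the floor at log2 5.57, and triangles mark arrays with bright spike-ins. Adrb1 averaged 6.54 in old and 8.39 in young, and 4 of 5 young arrays of Mybpc1 lay at the floor.

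Complement and acute phase genes, which serve innate defence, were higher in old as a group: 19 of 24 tested members were higher, with a median difference of 0.56, and 0 passed singly over all probe sets or adjusted over the list alone. C1s, a protease that starts the classical pathway, differed by 1.59 ± 0.45 (SE), Lbp, which binds lipopolysaccharide, by 1.68 ± 0.56, and C1qb, a recognition subunit of C1, by 1.08 ± 0.41. C1qc, another recognition subunit, differed by -0.11 ± 0.54. Cfd, the only tested gene that the list shares with the fat cell markers, differed by 1.69 ± 0.61. Acute phase members went both ways, with A2m at -0.66 ± 0.36, Serpina1 at -0.71 ± 0.76, Fgg at -0.58 ± 0.74 and Crp at 0.01 ± 0.45. Hp was at 0.89 ± 0.67, Orm1 at 0.56 ± 0.70, Serpina3n at 0.56 ± 0.66 and Cp at 0.46 ± 0.50. Camera called the complement list at the preset correlation (adjusted p = 0.00158), but not with an estimated correlation (adjusted p = 0.184). Its adjusted p ran from 8.33e-05 to 0.186 over 28 alternatives. Its mean per array lay above the young mean in 6 of 6 old arrays (9.28 ± 0.21 in old against 8.77 ± 0.20 in young, SD; exact permutation p = 0.00649, adjusted p = 0.143). Relative to all genes the list shifted by 0.50 ± 0.13 (SE between arrays), and by 0.57 ± 0.14 with the spike-in class as a block. Within the dim arrays the shift was 0.60, and within the bright arrays, which hold 1 young array, it was 0.51.

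Genes of the mitochondrial respiratory chain and citric acid cycle, which make most of the ATP of heart muscle, were lower in old as a group. Of 48 tested members 45 were lower, with a median difference of -0.39, and 0 passed singly over all probe sets or adjusted over the list alone. Among the examples, Ndufv2, a subunit of complex I, differed by -0.96 ± 0.28 (SE), Cox8a, a subunit of cytochrome oxidase, by -0.92 ± 0.33, and Cs, the citrate synthase, by -1.12 ± 0.48. Camera called the mitochondrial list at the preset correlation (adjusted p = 5.98e-05) but not with an estimated correlation (adjusted p = 0.383), with a range of 2.21e-08 to 0.383 over 28 alternatives. All 6 old arrays lay below the young mean (12.27 ± 0.33 against 12.67 ± 0.27, SD; exact permutation p = 0.0455, adjusted p = 0.2), and old replicate 6 stood lowest at 11.64. The 98th percentile of intensity was also lowest in old replicate 6, at 4993.5, against 7039.5 or more in the other arrays. Relative to all genes the list shifted by -0.41 ± 0.20 (SE between arrays), by -0.35 ± 0.24 with the spike-in class as a block, by -0.33 within the dim and by -0.38 within the bright arrays.

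Fatty acid oxidation genes were lower in old as a group, with 29 of 34 tested members lower and a median difference of -0.51, and 0 members passed singly or adjusted over the list alone. Acads and Acadvl, acyl-CoA dehydrogenases of short and very long chains, differed by -0.88 ± 0.33 (SE) and -1.10 ± 0.46, and Hadha of the trifunctional protein by -0.55 ± 0.25. Cpt1a, the liver form of the carnitine transferase, went the other way at 1.15 ± 0.59, while the muscle form Cpt1b differed by -0.57 ± 0.29. The call by camera held at the preset correlation (adjusted p = 1.39e-04), and did not with an estimated correlation (adjusted p = 0.303) or with the spike-in class as a block (adjusted p = 0.0738). Its range was 7.46e-06 to 0.395 over 28 alternatives. Its mean lay below the young mean in 6 of 6 old arrays (exact permutation p = 0.0368, adjusted p = 0.2). The list shift of -0.45 ± 0.17 (SE between arrays) became -0.25 ± 0.14 with the block, with -0.27 within the dim and -0.21 within the bright arrays.

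Heat shock proteins and chaperones were lower in old in 22 of 28 tested members, with a median difference of -0.30 and 0 members past the threshold singly or adjusted over the list alone. Hspb1, a small heat shock protein, differed by -0.95 ± 0.29 (SE), and Fkbp4, a co-chaperone of steroid receptors, by -1.65 ± 0.55. Camera called this list at the preset correlation (adjusted p = 0.00625), and did not with an estimated correlation (adjusted p = 0.36), with the spike-in class as a block (adjusted p = 0.262) or without young replicate 1 (adjusted p = 0.101) or 5 (adjusted p = 0.0544). Its range was 5.26e-05 to 0.897 over 28 alternatives. Its mean lay below the young mean in 6 of 6 old arrays (exact permutation p = 0.0411, adjusted p = 0.2). The shift of -0.39 ± 0.18 (SE between arrays) became -0.20 ± 0.16 with the block, with -0.36 within the dim and 0.07 within the bright arrays, where the direction turned.

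Glycolysis and glucose use genes were lower in old in 21 of 34 tested members, with a median difference of -0.29. Slc2a4, the insulin-dependent glucose transporter, differed by -0.95 ± 0.31 (SE), and Pygm, the muscle glycogen phosphorylase, by -0.79 ± 0.33. At the preset correlation camera called the list (adjusted p = 0.037) but not with an estimated correlation (adjusted p = 0.383). The call was lost without old replicate 3, 5 or 6 or young replicate 1, 3 or 5 (adjusted p = 0.0798 to 0.244). Its range was 0.00253 to 0.973 over 28 alternatives, and its mean lay below the young mean in 4 of 6 old arrays (exact permutation p = 0.134, adjusted p = 0.299). The shift of -0.25 ± 0.16 (SE between arrays) became -0.06 ± 0.13 with the spike-in class as a block, with -0.08 within the dim and -0.04 within the bright arrays.

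Fetal and hypertrophy-associated genes, which embryonic or overloaded heart muscle uses, were higher in old in 14 of 18 tested members, with a median difference of 0.38. The list shares 4 tested genes, Acta1, Myl4, Myl7 and Nppa, with the atrial, skeletal muscle, nerve and blood markers, which shifted by 0.39 ± 0.18 (SE between arrays), or 0.44 ± 0.21 with the block, and did not pass. Besides Mybpc1 and Nppa, Ankrd1, a stress-responsive muscle protein, differed by 0.62 ± 0.32 (SE). Over all probe sets 0 members passed, and 1, Mybpc1, passed when adjusted over the list alone (limma adjusted p = 0.0359). The list passed camera at the preset correlation (adjusted p = 0.0344) but not with an estimated correlation (adjusted p = 0.208). The call was lost without old replicate 3 or 4 or young replicate 3, 4 or 5 (adjusted p = 0.0544 to 0.136). Its range was 0.014 to 0.571 over 28 alternatives, and its mean lay above the young mean in 6 of 6 old arrays (exact permutation p = 0.0368, adjusted p = 0.2). The shift of 0.49 ± 0.22 (SE between arrays) became 0.36 ± 0.25 with the spike-in class as a block, with 0.18 within the dim and 0.65 within the bright arrays. Without old replicates 3 and 4, the arrays of high GAPDH ratio and the highest for this list at 10.43 and 10.71, it was 0.26 ± 0.19 (SE; camera adjusted p = 0.181).

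Macrophage and granulocyte markers were higher in old in 14 of 17 tested members, with a median difference of 0.26. The mean of the list lay above the young mean in 4 of 6 old arrays. Ccl4, a chemokine, differed by 1.67 ± 0.67 (SE), and Lyz2, the lysozyme of macrophages, by 1.49 ± 0.65. The list passed camera at the preset correlation (adjusted p = 0.0344) but not with an estimated correlation (adjusted p = 0.383). The call was lost without old replicate 1 or 3 or young replicate 1, 2 or 5 (adjusted p = 0.0671 to 0.179). Its range was 0.00335 to 0.872 over 28 alternatives, and the per-array means did not differ beyond chance (exact permutation p = 0.104, adjusted p = 0.299). The shift of 0.47 ± 0.27 (SE between arrays) was 0.43 ± 0.32 with the spike-in class as a block, with 0.56 within the dim and 0.23 within the bright arrays. For the glycolysis and macrophage lists, 0 members passed over all probe sets or adjusted over the list alone.

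**Figure D3:**
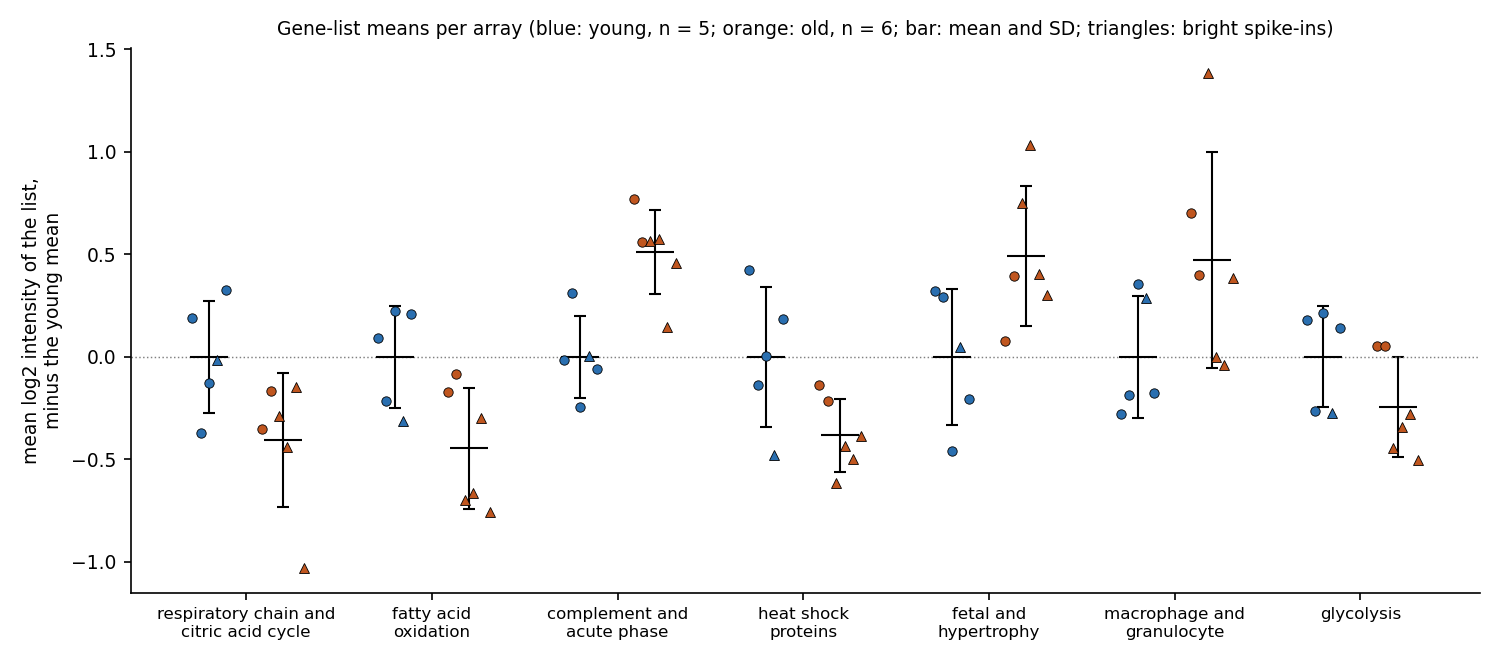
The mean log2 intensity of the 7 gene lists that passed camera, per array, minus the mean of the young arrays, with bars for mean and SD (young n = 5, old n = 6) and triangles for arrays with bright spike-ins. The complement list lay above the young mean in 6 of 6 old arrays and the mitochondrial list below it in 6 of 6, with old replicate 6 lowest.

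The other 15 lists did not pass, and 0 of their members passed over all probe sets or adjusted over the list alone. Adrenergic and adenosine receptor signalling, the pathway through which catecholamines drive the heart, had 29 lower and 20 higher among 49 tested genes, with a mean difference of -0.10 (camera adjusted p = 0.511). Camera gave an adjusted p of 0.151 for atrial, skeletal muscle, nerve and blood markers, 0.184 for adult sarcomere genes, 0.196 for ion channels and pumps, 0.214 for the cell cycle and 0.273 for calcium handling. It gave 0.317 for lymphocyte markers, 0.333 for both antioxidant enzymes and extracellular matrix genes, 0.336 for antigen presentation and 0.54 for immediate early genes. It gave 0.719 for circadian clock genes, whose median of 0.04 and mean of -0.05 differed in sign, 0.804 for endothelial and smooth muscle markers, and 0.824 for both apoptosis genes and fat cell markers.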

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

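The tests of spike-in class, with a preset or an estimated correlation, and of RNA degradation were chosen only after the data were seen. An array was singled out where its gap to the nearest array of its group was large for the group's range, which happened in 10 of 88 groups tested, where chance gives about 4.4.

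In young replicate 2, Mybpc1 read 8.19 on the log2 scale, while the other 4 young arrays lay at the floor of 5.57. Otc read 7.86 in young replicate 4, with the nearest young array at 6.04. Adrb1 read 7.16 in young replicate 3, with the nearest at 8.48. The mean spike-in signal was 11.97 in young replicate 4, with the nearest at 10.20. The mean of the mitochondrial list was 11.64 in old replicate 6, with the nearest at 12.23. Antigen presentation genes averaged 10.46 in young replicate 3, with the nearest at 9.98. Circadian clock genes averaged 8.99 in young replicate 5, with the nearest at 8.37. Ion channels averaged 8.15 in old replicate 3, with the nearest at 8.65. Endothelial and smooth muscle markers averaged 9.14 in young replicate 2, with the nearest at 8.77. Fat cell markers averaged 8.75 in young replicate 4, with the nearest at 9.27.

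Complement and acute phase genes were higher in the old samples, and the technical explanations tested removed little of this. Of 100 splits of the arrays, 2 reached its camera p, the real one included (2.16e-04 for the real split, 2.29e-05 for the smallest other). Chance cannot be excluded once the number of lists is counted (exact permutation p = 0.00649, adjusted p = 0.143). The values argue against compression of bright signals as the whole cause, since 0.01% of 10000 lists of matched signal lay as far. Such lists averaged 0.01, so little shift was predicted for this list, and they treat genes as independent. Relative to genes of matched signal the list shifted by 0.50 ± 0.13 (SE). With the spike-in class as a block the list passed at the preset correlation (adjusted p = 4.56e-04, range 8.33e-05 to 0.186 over 28 alternatives) but not with an estimated one (0.117 with the block, 0.184 without), with a shift of 0.57 ± 0.14 (SE) that 1 of 75 relabelings of age within the classes reached, the real one, against 0.49 at most otherwise (exact permutation p = 0.0133, the smallest possible, or 0.293 adjusted over lists). More macrophages in the old samples stay open, as the macrophage list's median of 0.26 had a bootstrap interval of 0.13 to 0.82 that holds the complement median of 0.56. This interval resampled the 17 genes of the list and not the arrays, between which its shift was 0.47 ± 0.27 (SE). Lyz2, its most abundant member, was at 11.63 ± 1.90 (SD) in old and 10.13 ± 0.38 in young. An effect of age may be the source, as a hypothesis found and tested on the same arrays.

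Lower mitochondrial genes in the old samples could not be set apart from chance, since 14 of 100 splits gave a camera p as small (2.72e-06 for the real split, 1.45e-11 for the smallest other). The tables argue against compression of bright signals as the whole cause, with 0% of 10000 lists of matched signal as far and a shift of -0.23 ± 0.11 (SE) relative to such genes, although matched lists treat genes as independent and averaged -0.17 of the list's -0.40, and with the spike-in block the shift was -0.25 ± 0.13, under 2 standard errors. Array quality cannot be told apart: with the spike-in class as a block the adjusted p was 4.56e-04 at the preset correlation (range 2.21e-08 to 0.383 over 28 alternatives) and 0.475 with an estimated one (0.383 without the block), and the shift went only from -0.41 ± 0.20 to -0.35 ± 0.24 (SE), which argues against it as the whole cause but is under 2 standard errors. Degradation of RNA in old replicates 3 and 4 is argued against as the whole cause, since without them the adjusted p was 8.52e-06 and the shift no smaller at -0.46 ± 0.25 (SE), but that too is under 2 standard errors and leaves it open. An effect of age may contribute and stays open; 14 of 75 relabelings within the classes gave a shift as large as -0.35 (0.72 at most), but missing that threshold excludes nothing at this standard error, so that bound was set wrongly.

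Fatty acid oxidation and heat shock genes were lower in the old and in the bright arrays at the preset correlation, and none of these calls held with an estimated one. Of 100 splits, the real one included, 2 reached the camera p of fatty acid oxidation (1.26e-05 for the real split, 1.09e-06 for the smallest other) and 7 that of heat shock (0.00114 and 1.36e-04). Chance cannot be excluded for either once the number of lists is counted (exact permutation p = 0.0368 and 0.0411, adjusted p = 0.2 for both). With the spike-in class as a block the adjusted p was 0.0738 for fatty acid oxidation, whose shift went from -0.45 ± 0.17 to -0.25 ± 0.14 (SE), and 0.262 for heat shock, whose shift went from -0.39 ± 0.18 to -0.20 ± 0.16 (SE), so the calls ended because the shifts shrank and array quality may account for part of both (ranges 7.46e-06 to 0.395 and 5.26e-05 to 0.897 over 28 alternatives). The tables argue against compression of bright signals as the whole cause for fatty acid oxidation (0.01% of 10000 matched lists; shift -0.34 ± 0.13, or -0.19 ± 0.11 with the block, SE) but leave it open for heat shock, where 0.07% met the bound set beforehand yet matched lists treat genes as independent and the shift of -0.31 ± 0.16 (SE) was under 2 standard errors even without the block. Degradation of RNA as the whole cause of the fatty acid oxidation pattern is argued against but not excluded (adjusted p = 0.00315 and shift -0.36 ± 0.20, SE, without old replicates 3 and 4), and age stays open, for 12 of 75 relabelings within the classes gave a shift as large as -0.25 (0.34 at most), which excludes nothing at a standard error of 0.14, so that bound too was set wrongly.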

How the results depend on the processing

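The fits with spike-in class or signal, without the arrays of high GAPDH ratio and within one spike-in class alone were chosen only after the data were seen. Each list had 28 alternatives, 23 of them chosen beforehand, and its value is camera's adjusted p. The cause of each change was not tested, except that fits on fewer arrays or fewer genes have less to test.

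The count of probe sets past the threshold in limma, 0 with 394 at an unadjusted p under 0.05, became 2 without old replicate 5, all higher in old, and ranged from 0 to 2 over the fits without 1 array. It was 1 in the dim arrays alone and 5 in the bright arrays alone, where the lone young array was assumed to vary like the old ones. The corresponding genes numbered 1 (dim) and 2 (bright), and 0 probe sets lower in old passed in any of 26 alternatives. Probe sets at an unadjusted p under 0.05 numbered 258 with the spike-in covariate, 262 without the arrays of high GAPDH ratio, 116 in the bright arrays alone, and 296 to 482 without 1 array.

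With an estimated correlation, 0 of the 7 called lists passed: the adjusted p was 0.184 for complement, 0.208 for fetal genes, 0.303 for fatty acid oxidation, 0.36 for heat shock, and 0.383 for the mitochondrial, macrophage and glycolysis lists. With the spike-in class as a block, fatty acid oxidation had 0.0738, fetal genes and macrophage markers 0.111 each, heat shock 0.262 and glycolysis 0.62. With the spike-in covariate, fatty acid oxidation, fetal genes and macrophage markers had 0.144 each, heat shock 0.245 and glycolysis 0.891. Without the arrays of high GAPDH ratio, glycolysis had 0.0889, macrophage markers 0.0937 and fetal genes 0.181. In the dim arrays alone, fetal genes had 0.571 and glycolysis 0.521, and the cell cycle list passed at 0.0429. In the bright arrays alone, the mitochondrial list had 0.118, complement and fetal genes 0.186 each, fatty acid oxidation 0.395, macrophage markers 0.872 and glycolysis 0.973, and heat shock turned to the opposite direction at 0.897.

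Among other choices, no filter gave 0.0727 for both complement and fetal genes, and the floor at the 40th percentile gave fetal genes 0.0647 and array weights gave them 0.137. Quantile normalization gave macrophage markers 0.085 and glycolysis 0.228, and the filter at the 60th percentile gave glycolysis 0.051 and atrial, skeletal muscle, nerve and blood markers 0.0478. The mean of all probe sets of a gene gave adult sarcomere genes 0.0488. Quantile normalization shifted the median log2 difference of all tested probe sets by -0.107, median centring by -0.118 and no filter by 0.122. At an unadjusted p under 0.05, quantile normalization gave 123 higher and 241 lower and median centring 131 and 295, against 178 and 216 with the deposited scaling. The balance turned with no filter (342 higher, 243 lower), no trend (212 and 176), array weights (285 and 276) and the bright arrays alone (88 and 28).

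Leaving out 1 array at a time gave adjusted p ranges of 0.014 to 0.136 for fetal genes, 0.00391 to 0.244 for glycolysis, 0.00545 to 0.179 for macrophage markers and 3.09e-04 to 0.101 for heat shock. The range was 0.0337 to 0.451 for the cell cycle list, which passed without young replicate 4. Calls were lost without old replicates 3 and 4 and young replicates 3, 4 and 5 for fetal genes, old replicates 3, 5 and 6 and young replicates 1, 3 and 5 for glycolysis, old replicates 1 and 3 and young replicates 1, 2 and 5 for macrophage markers, and young replicates 1 and 5 for heat shock. The complement, mitochondrial and fatty acid oxidation calls held without any 1 array (highest adjusted p 0.0154, 0.00619 and 0.00453).

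The replicate block ended the glycolysis call (0.174) and left 0 probe sets past the threshold, with 393 at an unadjusted p under 0.05. Equal replicate numbers did not pair the arrays: only 1 of 5 young arrays correlated best with the old array of its number (r from -0.251 to 0.246). Uncalled lists changed sign in 28 of 420 comparisons. Named genes changed sign in 16 comparisons, which came from 3 of 16 genes. The RNA integrity ratios passed in none of 11 fits without 1 array. Signal near the floor limits the differences that dim genes can show.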

Other observations

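The contrast between spike-in classes, its alternative with an estimated correlation and the genes singled out here were chosen only after the data were seen.

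Among 857 genes with at least 2 tested probe sets, 20 had 2 or more at an unadjusted limma p under 0.05 in the same direction, 5 higher and 15 lower in old, and none of their probe sets passed over all those tested. Maoa, the monoamine oxidase that breaks down noradrenaline and serotonin, was higher by 1.86 to 2.37, and Gsta1, a glutathione transferase, by 1.23 to 2.60 through probe sets that can read related genes. Rpl3, a ribosomal protein, was higher by 0.96 to 1.19. Fkbp4, a co-chaperone, differed by -2.39 to -1.65, Dusp1, a phosphatase that ends MAP kinase signals, by -1.88 to -1.87, and Ccnd3, a D-type cyclin, by -1.72 to -0.93. Some of these probe sets share probes. Chance cannot be excluded for this count, since 6 of 100 splits of the arrays gave 20 or more, with 32 as the highest other.

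For the whole comparison, chance cannot be excluded for the 394 probe sets at an unadjusted limma p under 0.05, since 13 of 100 splits gave as many. The highest other split gave 586, with 6 probe sets past the threshold, and it put all 5 bright arrays into the group of 6, while the next highest, with 572 and 563, held 3 of them there; with the spike-in class as a block the age comparison had 268. For the count of 0 past the threshold the splits say nothing, since all 100 must give as many, with 6 as the highest other. At the preset correlation, 2 of 100 splits, the real one included, called 7 lists or more, with 8 as the highest other. This met the bound set beforehand for the count, but it rests on that correlation, so chance is not excluded. The count was 0 with an estimated correlation and 2 with the spike-in class as a block, and these were not set against other splits. Chance cannot be excluded for fetal genes (5 of 100, camera p 0.00831 against 0.0017 for the smallest other) or glycolysis (9 of 100, camera p 0.0118 against 1.73e-04). The same holds for macrophage markers (20 of 100, camera p 0.00939 against 1.08e-05).

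Bright and dim arrays differed in 64 probe sets with age in the model (limma, adjusted over 5244), 22 higher and 42 lower in the bright arrays, with 699 at an unadjusted p under 0.05. In the same model 0 differed with age, and 268 had an unadjusted p under 0.05. Tpm3 (L24776_at), a tropomyosin, was higher in the bright arrays by 5.25 ± 0.66 (SE), while Pln, the phospholamban that restrains the calcium pump, differed by -2.32 ± 0.37. Casq2, which stores calcium in the sarcoplasmic reticulum, differed by -1.90 ± 0.35. The probe set Z12158cds_at of Pdha1, a subunit of pyruvate dehydrogenase, differed by -3.65 ± 0.53. The brighter probe set that stands for Pdha1, rc_AA799598_at, was not among the 64. At the preset correlation camera called fatty acid oxidation (adjusted p = 0.0388), glycolysis (0.0388) and heat shock genes (0.039) as lower in the bright arrays, and neither the mitochondrial (0.522) nor the complement list (0.612). With an estimated correlation camera passed 0 lists, with 2 at an unadjusted p under 0.05, and gave adjusted p of 0.4, 0.409 and 0.374 for the 3 called ones.

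An age effect common to both classes was tested as a hypothesis of this re-analysis. The old minus young differences in the dim and in the bright arrays correlated across genes, which are not independent replicates, at r = 0.10, and 19 of 75 relabelings of age within the classes gave a correlation as high, with 0.22 as the highest other. The bound set beforehand would have counted against such an effect, but it was set wrongly, since the bright class holds 1 young array and a missed threshold there excludes nothing.

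In young replicate 4, Hbb, a beta-globin, read 9.21 against 13.67 to 17.41 in the other arrays, and Hbb-b1 read 9.29 against 12.36 to 15.70. The probe set M27467_at of Cox6c, a cytochrome oxidase subunit, read 6.10 and 5.65 in old replicates 1 and 2 and 11.52 to 15.32 in old replicates 3 to 6, while its other probe set, M27466_at, lay between 9.45 and 11.12 in all arrays. The 5 probe sets past the threshold in the bright arrays alone were this one of Cox6c, those of Hbb and Hbb-b1 and 2 without a single gene symbol, and their calls rest on young replicate 4 as the only young array. In the dim arrays alone, the probe set S45812_s_at of Maoa differed by 3.32 ± 0.42 (SE, limma adjusted p = 0.0442), with 2 old arrays at 13.94 and 12.96. Over all arrays its difference was 1.86, and old replicate 5 read 9.17, below the lowest young array at 9.47.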
